A study of Caenorhabditis elegans with 8 samples.

How the data were processed

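Per the labels' protocols, worms were grown at 20 °C from synchronized eggs, RNA was extracted with Trizol, 100 ng of total RNA was depleted of ribosomal RNA, and strand-specific libraries were made with a stranded total RNA kit and 15 cycles of PCR. The libraries were read on 1 lane as 50 nt paired ends. The molecule label names polyA RNA instead, and this conflict was left open. The submitters' processing notes name FastQC 0.11.3, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks and Cuffdiff 2.1.1. The genome build, the gene annotation, the counting tool's version and its strand setting are not given in the sources used here.

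The authors deposited a table of raw counts with 45461 rows, of which 32245 had no count in any library. No normalization is recorded for these deposited counts and their totals differ between libraries. The table has 2 further columns of values that match no sample in the labels, which were not used in any step. No row names something other than a gene, so no share of unassigned reads could be given. Row names were matched to the Ensembl annotation of WBcel235: 44933 rows matched 1 gene and 528 did not, and the latter held 0.363% of counts. A gene was taken as lying opposite a row when it was the 1 protein-coding gene on the other strand sharing at least 20 exon bases, and a row as nested when at least 90% of its exon bases were shared. Host and nested rows were compared as counts per exon base wherever either held at least 80 counts.

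Groups follow the redox characteristic in the labels. The titles name no redox state: they read High for libraries labelled reduced and Low for those labelled oxidized, in replicate 5 too. For replicate 5 the source name gives the opposite state, so fits without it and with its labels exchanged were listed as alternatives. Same-numbered libraries share a date in their titles (June28 for 1 and 2, July7 for 3, August6 for 5), which was taken as pairing them. Within June28 the date does not pair them, and only the replicate number does. Some titles also hold R4 or R5. Both libraries of replicate 2 read R4, while in replicates 3 and 5 the reduced library reads R4 and the oxidized R5. What R4 and R5 stand for was not settled, and in those replicates it cannot be told apart from the group. The deviations of same-numbered libraries from their group means correlated at 0.06, −0.16, 0.13 and 0.30 (mean 0.08, against −0.03 for other pairs), across rows that are not independent. Other pairs ran from −0.46 to 0.41, the highest being oxidized replicate 1 with reduced replicate 2, so the values do not settle the pairing. No 2 libraries had identical counts, and Spearman correlations between libraries ran from 0.69 to 0.84.

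Rows were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, without a block, with a Benjamini-Hochberg adjusted p threshold of 0.05. The design written before the data were examined did not name the legacy argument of glmQLFit. The alternatives written at the same time list legacy = TRUE, so legacy = FALSE was used. A first exploratory fit had used legacy = TRUE, the default of this version, and its 3 calls had been seen before the setting was settled; both counts are given. CPM values use TMM-scaled library sizes. Common dispersion was 0.339, a coefficient of variation of 58.3%. Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 3 members were tested, with an estimated correlation and fry beside it. DESeq2 1.42.0 and limma voom ran on the same filtered rows; for DESeq2, lists were tested on its Wald statistics. Coordinates and overlaps were handled with Python 3.11.15 and bedtools 2.31.1.

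Rows were named by a rule fixed before the data were examined: up to 12 per direction with the largest change among those past the threshold, with a mean of at least 5 CPM and the same sign in all 4 pairs; 15 fixed genes; and up to 4 members with the smallest p for each list discussed. Had fewer than 5 rows passed, the rule would have named 8 rows per direction by p instead, so the exploratory fit with 3 calls would have taken that path. Library composition was tested by exact two-sided permutation on 3 measures fixed before the data were examined. A further 3 measures (shares of ribosomal protein and collagen rows, and the ratio of host to nested rows) were added after seeing the data and adjusted as a separate family. For the check of replicate 5, rows were chosen in fits without 1 replicate, and their direction in the pair left out was read from TMM-scaled CPM with 0.5 added.

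On counts simulated from the real means, dispersions and library sizes for 2315 rows, with 200 changed rows in each of 5 draws, the test called 16.3% of 2-fold, 62.6% of 4-fold and 92.6% of 8-fold changes, and 0.439% of unchanged rows. With the replicate block it called 8.7%, 51.7% and 85.4%, and 0.267% of unchanged rows. A list of 40 rows shifted by 1 on the log2 scale passed in 5 of 5 draws and an unchanged list in 0 of 5. All simulated rows were drawn independently and with no replicate effect. In the real data the body wall muscle and cytosolic ribosomal protein lists had estimated correlations of 0.374 and 0.805. The simulation therefore does not show how often lists of correlated rows pass, or how the block performs in these data. An adjusted p threshold is also less strict when 200 rows change than when few do. In the real data 5 rows passed, so the simulated shares called may be higher than those that apply there. Alternatives covered scaling, filtering, tool, dispersion, block, replicate 5, each library left out, abundant rows and biotypes. Reading rows as the gene on the other strand, and legacy = TRUE with robust estimation kept, were added after seeing the data.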

Results

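RNA was measured in Caenorhabditis elegans larvae at the L2 stage that carried Prpl-17::Grx1-roGFP2, a fluorescent sensor whose signal reports whether the glutathione pool is oxidized or reduced. The labels divide the worms into an oxidized and a reduced population, with 4 biological replicates of each, numbered 1, 2, 3 and 5, and about 10000 worms per replicate. Per library the count table held between 635990 counts (oxidized replicate 3) and 1089259 counts (oxidized replicate 1), spread over 5058 to 7548 rows with at least 1 count. At this depth 3 counts, taken as the floor, corresponded to between 2.75 and 4.72 CPM (counts scaled to library size), which covers counting error only.

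The table's rows did not measure the genes they are named after in a simple way. Rows of the 12 protein-coding genes of the mitochondrial genome, which are among the most abundant transcripts of animal cells, held 190 counts in all 8 libraries together, or 0.00297% of the total. Where a small non-coding gene lies inside an exon of another gene on the opposite strand, the inner row held the higher count density in 169 of 185 such pairs. The row of act-1, an actin gene, held 164 counts, while the row of T04C12.30, annotated inside it on the other strand, held 15626. The row of sca-1, the calcium pump of the endoplasmic reticulum, held 203 counts, against 48203 for K11D9.5 inside it. For this reason the text speaks of rows, and for rows called higher gives the protein-coding gene on the other strand where 1 shares at least 20 exon bases. Most other rows are named without it, which does not mean that nothing lies opposite them.

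**Figure D1:**
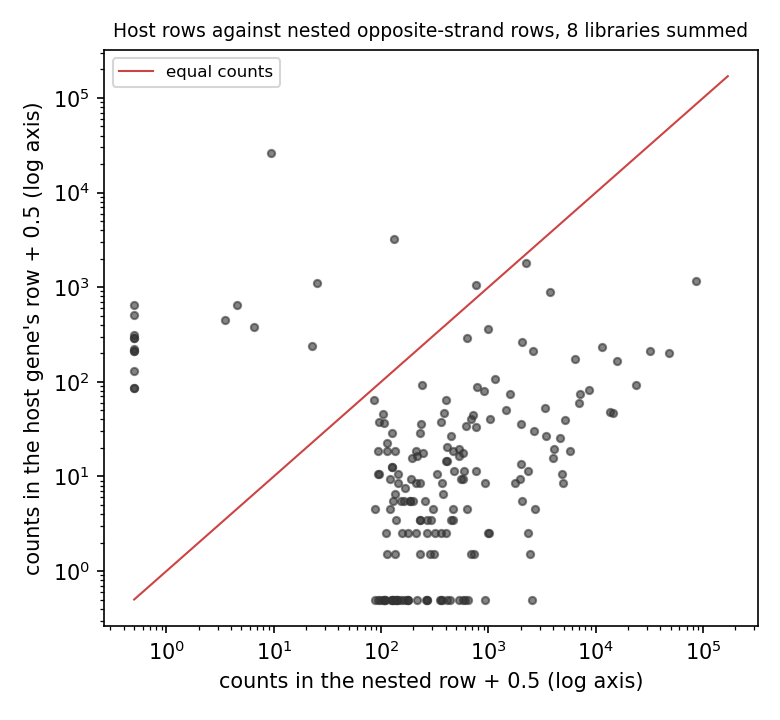
Each point is a gene (host) with a non-coding gene nested inside its exons on the opposite strand. Axes give the counts of both rows summed over the 8 libraries, with 0.5 added, on log axes, and the line marks equal counts. In 169 of 185 pairs the host row had the lower count density per exon base, which is not the same as lying below the line.

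The comparison of oxidized with reduced worms asked which transcripts differ between larvae of the same age that differ in redox state. Of 2315 rows tested, 5 were higher in oxidized worms and 0 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 69 higher and 53 lower rows, 122 in all, where chance alone gives about 116. DESeq2 called 9 higher and 0 lower, and limma voom 3 higher and 0 lower. With the replicate number as a block, edgeR called 11 higher and 4 lower, and all 5 rows were among them.

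The 5 rows included ones that overlap, on the other strand, a cuticle collagen gene, a hedgehog-related gene and an apical matrix gene. The row of F12F6.17, a non-coding gene inside the exons of the cuticle collagen gene col-128, stood at 89.7 ± 18.6 CPM in reduced and 561 ± 46.2 in oxidized worms (SD, n = 4), a log2 fold change of 2.65 (SE 0.37, edgeR adjusted p = 0.000388). The pccb-1 row, named for a subunit of propionyl-CoA carboxylase, rose from 459.8 ± 267 to 2173 ± 211 CPM, by 2.24 on the log2 scale (SE 0.36, adjusted p = 0.00251). Its exons share 43 bases with wrt-2, a hedgehog-related gene on the other strand. The row of C09F12.6, a non-coding gene that shares 110 bases with lpr-3, which encodes a lipocalin-related protein of the apical matrix, had a log2 fold change of 2.53 (SE 0.53, adjusted p = 0.0408). The nhr-8 row, named for a nuclear hormone receptor, rose from 565.5 ± 204.6 to 2058 ± 620.1 CPM, by 1.87 (SE 0.35, adjusted p = 0.0126), and its exons share 47 bases with F33D4.6. The col-149 row, named for a cuticle collagen, had a log2 fold change of 3.75 (SE 0.82, adjusted p = 0.0408). It had 0 counts in reduced replicates 1 and 2, 3 in replicate 3 and 15 in replicate 5, against 16 to 116 in the oxidized libraries, so its fold depends on the prior count; its exons share 18 bases with the other strand's. Each of the 5 rows was higher in the oxidized library of all 4 pairs.

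In the annotation used here (WBcel235, from Ensembl; the authors' build is not given in the sources used here) F12F6.17 spans chromosome IV 11550413 to 11550631, inside col-128 at 11550002 to 11551960. The pccb-1 gene spans chromosome X 3089549 to 3092437 and meets wrt-2, at 3092395 to 3094349, at their 3′ ends. The nhr-8 gene spans chromosome IV 7710983 to 7714210 and meets F33D4.6 at 7714164 to 7718016. The C09F12.6 gene lies on chromosome X at 11057372 to 11057510, and lpr-3 at 11057401 to 11059793. The own rows of the genes on the other strand were low, with 35 counts over the 8 libraries for col-128, 30 for lpr-3, 101 for wrt-2 and 150 for F33D4.6.

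**Figure D2:**
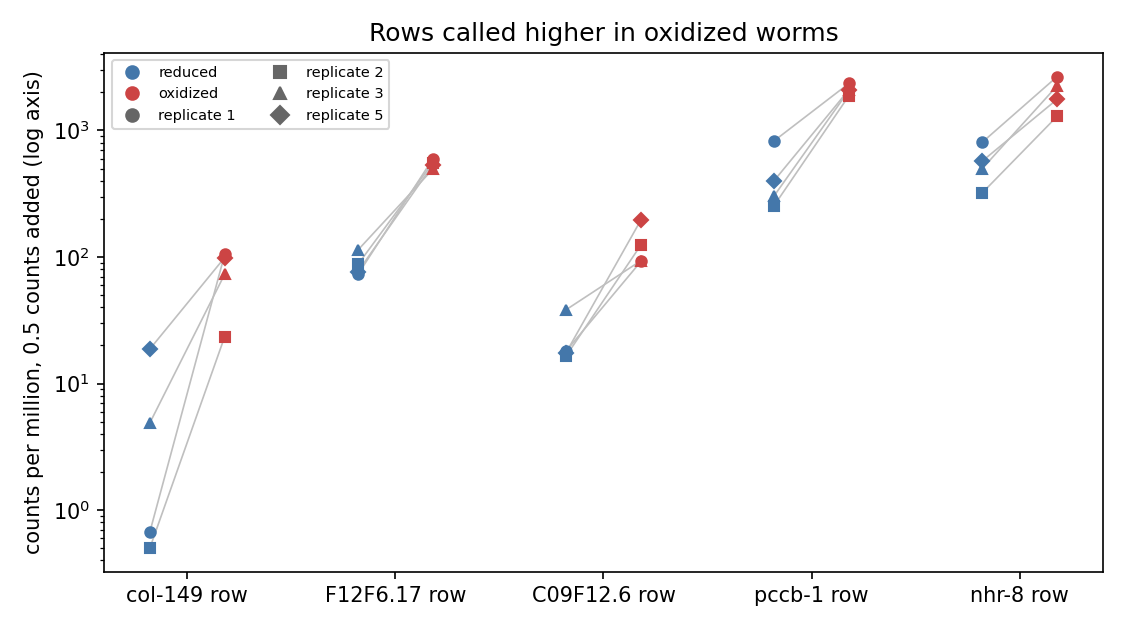
CPM (0.5 counts added, log axis) of the 5 rows called higher, in each library. Colour gives the group, the symbol the replicate number, and grey lines join libraries of the same number. Every oxidized library lies above the reduced library of its number.

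Which of these rows passed varied with the libraries used. F12F6.17 alone passed in every fit that left out 1 library. The number of higher rows was 1 without reduced replicate 3, 2 without reduced replicate 2 or oxidized replicate 3, and 3 without oxidized replicate 5. It was 4 without oxidized replicate 1 or reduced replicate 5, 6 without oxidized replicate 2 and 12 without reduced replicate 1. These fits also had fewer libraries, so a lost call need not mean that the row depended on the library left out. For replicate 5 a further label gives the opposite redox state; without both of its libraries 4 rows were higher, and with its labels exchanged 0 were.

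Cuticle collagens were the one fixed list with several members past the test when the list was adjusted by itself. Of 83 collagen rows tested, 1 rose and 0 fell over all rows tested, and 4 rose and 3 fell adjusted over the list alone. With the replicate block, 4 rose (col-149, dpy-3, sqt-1 and sqt-3) and 3 fell (col-147, col-80 and col-146) over all rows; sqt-3, col-147 and col-146 were named after their values were seen. The calls varied with the pairs used: the block called 0 collagen rows in either direction without replicate 3 or without replicate 5. It called 3 higher and 1 lower without replicate 2, and 4 higher and 3 lower without replicate 1. These fits had fewer libraries, so a lost call need not mean that it depended on the pair left out. The col-147 row shares 228 exon bases with T06E4.5 on the other strand, and the sqt-3 row held 26235 counts against 9 for F23H12.13, nested inside it on the other strand. Without the block the dpy-3 row had a log2 fold change of 2.98 (SE 0.71, adjusted p = 0.0831), the sqt-1 row 1.58 (SE 0.40, adjusted p = 0.131) and the col-80 row −2.01 (SE 0.54, adjusted p = 0.174). As a set the collagens did not pass (camera adjusted p = 0.547). Collagen genes resemble each other, so reads may be split between them in a way the counts do not show.

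**Figure D3:**
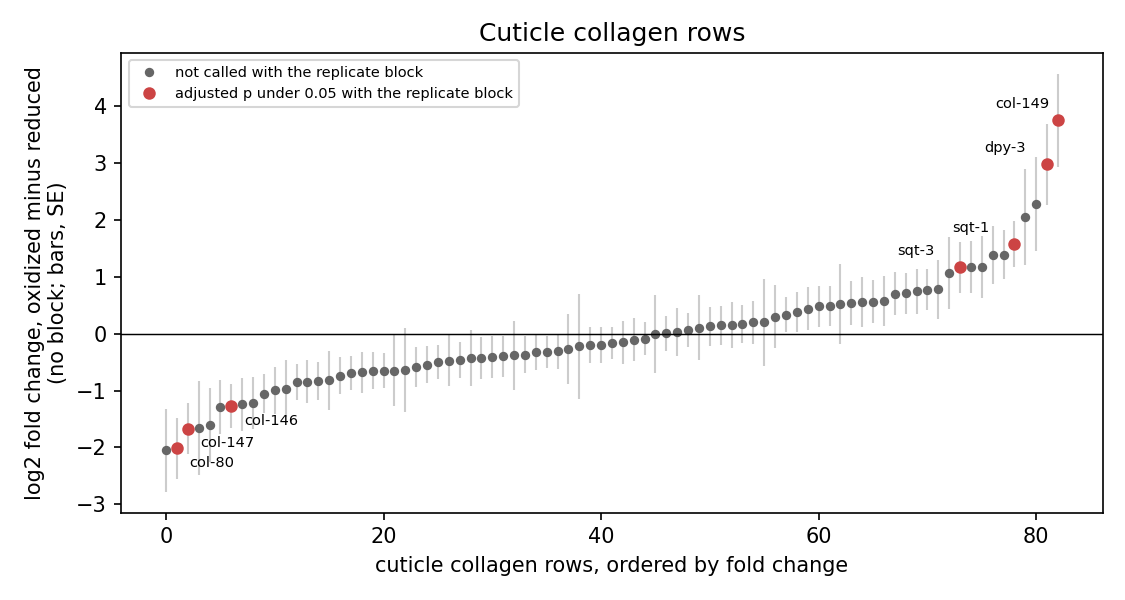
Log2 fold change, oxidized minus reduced, of the 83 tested cuticle collagen rows, ordered by size, with bars for the SE. Filled red points are the 7 rows with an adjusted p under 0.05 in the fit with the replicate block, of which 4 lie above 0 and 3 below.

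Of 40 gene lists fixed in advance, 27 had at least 3 tested rows, and 2 passed with a preset correlation. Body wall muscle rows were lower in oxidized worms, with 24 of 27 members below 0 and a median log2 fold change of −0.44 (camera adjusted p = 0.0107; adjusted p = 0.866 with an estimated correlation). None of its members passed, over all rows or adjusted over the list alone: the myo-3 row, named for a myosin heavy chain, had −1.32 (SE 0.59), tnt-2 −0.85, unc-54 −0.76 and deb-1 1.102. Cytosolic ribosomal protein rows were also lower, with 66 of 78 below 0 and a median of −0.22 (camera adjusted p = 0.0292; adjusted p = 0.866 with an estimated correlation). None of these passed either, and the lowest p belonged to rpl-7A (−0.77), rps-22 (−0.79), rpl-22 (−0.61) and rps-15 (−0.65). The direction of the ribosomal list turned when reduced replicate 2 was left out. The share of ribosomal protein rows ranged from 1.63% to 5.75% of counts between libraries, with 3.16% ± 1.79 in reduced and 2.71% ± 1.36 in oxidized worms (SD, n = 4; exact two-sided permutation p = 0.686). The other 25 lists had adjusted p from 0.0515 to 0.986.

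Genes of histone H3 lysine 4 methylation and of the stress response, chosen in advance from the study's title, were mostly too low to test. Of 15 such genes, the rows of rbr-2, prdx-2 and rpl-17 were tested, and none passed. The rbr-2 row, named for an H3K4 demethylase, had a log2 fold change of 0.61 (SE 0.72, adjusted p = 0.999), the row of prdx-2, a peroxiredoxin, −0.20 (SE 0.59, adjusted p = 0.999) and the row of rpl-17, whose promoter drives the sensor, −0.08 (SE 0.38, adjusted p = 0.999). The methyltransferase complex genes set-2, ash-2 and wdr-5.1 held 8, 9 and 9 counts in all 8 libraries together. The regulators hsf-1, daf-16, skn-1 and daf-2 held 30, 21, 31 and 19 counts, gcs-1 held 19, hsp-70 held 14 and sod-3 held 3, and hsp-16.2 and gst-4 held 0. These own rows held too few counts for a test. Rows that overlap sod-3, daf-16 and rbr-2 on the other strand, a reading added after the data were seen, held 654, 204 and 1986 counts, and none passed: log2 fold changes were −0.626 (SE 0.493, adjusted p = 0.966) at sod-3, 0.117 (SE 0.562, adjusted p = 0.998) at daf-16 and 0.132 (SE 0.296, adjusted p = 0.998) at rbr-2.

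Library composition did not separate the groups. Total counts were 820100 ± 54500 in reduced and 781800 ± 209000 in oxidized libraries (SD, n = 4; exact two-sided permutation p = 0.83). Rows detected numbered 6313 ± 990 and 6695 ± 584 (exact permutation p = 0.486), and the 10 most abundant rows took 34.5% ± 3.35 and 34.05% ± 3.14 of counts (exact permutation p = 0.857). All 3 had an adjusted p of 0.857, and the smallest p that the 70 relabellings can give is 0.0286.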

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

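The tests of strand, of moulting phase and of a leak between the groups were chosen after the results they bear on were seen; so was the test of replicate 5 on rows chosen without it. The exchange of its labels and the tests of other splits and of the ribosomal share were written before.

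Of 54 groups of 4 values checked for a sample far from the others, 1 stood out, where chance gives about 2.7. In the C09F12.6 row, reduced replicate 3 had 38.5 CPM, while the other reduced libraries lay between 16.7 and 17.9.

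Of 2315 tested rows, 1060 lay opposite 1 coding gene, and abundant rows were among them. The tables argue against antisense transcription counted on the right strand, since that leaves the host genes' own transcripts in place, while the median ratio of host to nested count density was 0.000399 and mitochondrial protein-coding rows held 0.00297% of counts. A candidate explanation is that a strand-specific library was counted with the opposite strand setting, which both values fit. The median ratio is also lowered by nested rows shorter than the reads. The 16 of 185 pairs that go the other way, and abundant collagen rows with no annotated gene opposite them, stay open. If the opposite strand setting was used, the pccb-1, F12F6.17, C09F12.6 and nhr-8 rows may hold reads of wrt-2, col-128, lpr-3 and F33D4.6, in that order.

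Several changed rows lie in or opposite cuticle collagen, hedgehog-related and apical matrix genes, and no explanation tested for this was excluded. Whether called rows lie in such genes more often than other rows was not tested. The block also called other rows, named after their values were seen. H42K12.3, F53B1.2 and C44H4.10 were higher, and T04F8.8 was lower (log2 fold change −1.45 with the block). F53B1.2 and C44H4.10 share exon bases with bus-5 and sym-1 on the other strand. Of the fixed list of moulting genes, 0 of 7 tested rows were called (camera adjusted p = 0.547). Read from the other strand, 0 of 3 moulting genes were called (camera adjusted p = 0.695). A leak of reads onto the wrong strand that differed between the groups would move collagen rows one way. With the replicate block at least 3 were called in each direction, but 0 without replicate 3 or without replicate 5, so a leak cannot be told apart from other causes. The ratio of host to nested rows was 8.738% ± 2.59 in reduced and 14.35% ± 7.95 in oxidized libraries (SD, n = 4; exact permutation p = 0.229, adjusted p = 0.687), and higher in oxidized in 3 of 4 pairs. The ratio is no clean measure of a leak, because the sqt-3 row, called higher with the block, is among its hosts. That row held 26235 counts, against 3242 for lpr-2, the next highest host of the pairs compared. The ratio without sqt-3 was not computed. Exchanged labels in replicate 5 cannot be told apart either. After the exchange 0 rows were called, but chance was not excluded for the 5 called before it, and the lists past the threshold went from 2 to 6, with the collagens at an adjusted p of 0.0461. Of 126 rows with an unadjusted p under 0.05 in the fit without replicate 5, 69.8% differed in the same direction in replicate 5, as did 4 of the 4 rows called; this share was 38.9%, 60.4% and 76.5% when replicate 1, 2 or 3 was left out instead. A different phase of the moulting cycle in the groups is a candidate biological explanation, and it too cannot be told apart: on genes read from the other strand, 4 hedgehog-related genes passed as a list (camera adjusted p = 0.00542) and not with an estimated correlation (adjusted p = 0.468). Without wrt-2 the other 3 did not pass (adjusted p = 0.734).

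Chance was not excluded as the source of the count of 5 rows. Of 35 splits of the 8 libraries, 2 gave as many, the real one included, a share of 5.71%. The other was reduced replicates 1 and 5 with oxidized replicates 2 and 5 against the rest, and it gave 90 rows. This points to a structure of the libraries that the labels do not name. These 4 libraries had the lowest shares of ribosomal protein rows, 1.63% to 2.34%, against 2.85% to 5.75% in the rest. They also had the highest shares of non-coding nested rows with hosts other than ribosomal protein genes, 7% to 7.64% against 4.84% to 5.79%. Among the 8 splits that part all 4 pairs, the others gave 0 rows. With the replicate block the real split gave 15 rows and the highest other 5, but 8 splits are too few for a share under 0.05. For gene lists, 20 of 35 splits gave at least 2, with up to 13 in another split, so chance was not excluded for the muscle and ribosomal lists.

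The share of ribosomal protein rows differed 3.53-fold between libraries, within both groups. It is possibly a leak of wrong-strand reads that varies by library: over the 8 libraries it correlated with the ratio of host to nested rows at Pearson's r = 0.568 (permutation p = 0.145) and Spearman's rho = 0.738 (permutation p = 0.0458), the single relation computed. Without oxidized replicate 1 and reduced replicate 5, the farthest from the median, r was 0.381. The ratio is weighted to the sqt-3 row, which held 26235 counts against 3242 for lpr-2, the next highest host. That row was called higher in oxidized worms with the block, and r without it was not computed. These values therefore do not measure a leak over the other hosts. With 8 libraries a leak cannot be told apart from other causes. Each date holds at most 4 libraries, too few for a value within it. A leak across all genes would also reach the mitochondrial protein-coding rows, which held 0.00297% of counts. That share is of all counts and not of mitochondrial reads, so it cannot show whether a leak of that breadth was present.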

How the results depend on the processing

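The fits with legacy = TRUE and robust estimation kept, and those on rows regrouped by the gene on the other strand, were chosen after seeing the data. The count of 5 higher rows became 9 without a filter and with DESeq2, 3 with limma voom and with legacy = TRUE (robust or not), 11 with the replicate block, 10 with the replicate block by title date, 0 with the labels of replicate 5 exchanged, and 1 on nested rows regrouped by the gene on the other strand. Leaving out 1 library gave 1 to 12. The count of 0 lower rows became 1 without a filter, 4 with the replicate block and 2 with the block by date; leaving out 1 library gave 0 to 3, the 3 without reduced replicate 1. The counts with the block also changed when a pair was left out. They were 18 higher and 4 lower without replicate 1, 7 and 2 without replicate 2, 2 and 0 without replicate 3, and 3 and 0 without replicate 5. The stricter filter kept 2395 rows, more than the 2315 of the filter used, so it tested nothing stricter. For these changes the cause was not tested, except that fewer libraries or rows entered some fits.

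The count of 2 lists became 4 with upper-quartile factors and without replicate 5, 6 with the labels of replicate 5 exchanged, 1 on protein-coding rows, with fry and on rows regrouped by opposite-strand gene, and 0 without a filter and with an estimated correlation; leaving out 1 library gave 0 to 4. The adjusted p of the muscle list was 0.103 without a filter, 0.866 with an estimated correlation and 0.876 with fry, and 1.32e-05 to 0.478 leaving out 1 library. That of the ribosomal list was 0.0591 without a filter, 0.0851 on protein-coding rows, 0.866 with an estimated correlation and 0.876 with fry, and 2.03e-11 to 0.999 leaving out 1 library, turning direction without reduced replicate 2. The collagen list turned direction without a filter (adjusted p = 0.905) and passed with replicate 5 exchanged (0.0461); leaving out 1 library gave 0.24 to 0.995, with the direction turned without reduced replicate 1, reduced replicate 2 or oxidized replicate 2. The replicate block changed no list's call. The list that passed with fry was the nuclear hormone receptors (fry adjusted p = 0.0211), and the 1 on regrouped rows was the hedgehog-related list. Neither is one of the 2 lists that passed with camera on the rows as deposited.

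Among named rows, F12F6.17 passed in all alternatives that tested it (it is not protein-coding) except the exchange of replicate 5, where its log2 fold change was 1.11. The col-149 and C09F12.6 calls were lost in 11 alternatives each, nhr-8 in 4 and pccb-1 in 2, all with the direction kept. Leaving out 1 library turned the sign of 3 rows that had not passed: prdx-2 ran from −0.68 to 0.066, rpl-17 from −0.33 to 0.25 and rps-15 from −1.43 to 0.35. Without replicate 5 the difference in total counts, oxidized minus reduced, was 3755 instead of −38270, and that in the share of the 10 most abundant rows 1.2 instead of −0.47 percentage points; neither passed. At no more than 1089259 counts per library 2315 rows were tested and most stress and chromatin genes were not; how far depth or the counted strand accounts for this was not tested.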

Other observations

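All tests in this part were chosen after the data were seen. When rows were regrouped by the gene on the other strand, 1033 genes could be tested, of which 5 were higher and 0 lower in oxidized worms (edgeR, 64 at an unadjusted p under 0.05). They were col-128 (log2 fold change 2.59, SE 0.30), wrt-2 (2.19, SE 0.34), F33D4.6 (1.85, SE 0.32), lpr-3 (2.47, SE 0.48) and bus-5 (1.37, SE 0.31), the last a gene whose mutants have an altered cuticle surface. Their adjusted p ran from 1.46e-05 to 0.0476, and each was higher in oxidized worms in 4 of 4 pairs. With the replicate block 7 were higher and 3 lower. For col-128, wrt-2, F33D4.6 and lpr-3 the rows on the other strand are among those called above. The F53B1.2 row, opposite bus-5, did not pass among the 2315 rows (log2 fold change 1.43, edgeR adjusted p = 0.0831). The bus-5 call was made among fewer tested genes. All are counts already tested as rows, read as another gene, and add no independent evidence.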
